A study of Neodesmus pupukensis with 4 samples.

How the data were processed

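Gene expression was measured by RNA sequencing in 4 libraries of the microalgal strain UTEX2341, 1 from each of 4 culture times (14, 45, 57 and 88 h). Total RNA was extracted with TRIzol, a phenol reagent, and libraries were made by standard Illumina protocols, per the labels' protocols. BWA, a short-read aligner, is named per the submitters' processing notes, without a version. The reference, the assembler, the annotation, read filtering, strandedness and the treatment of reads that match several sequences are not given in the sources used here. The identifiers have the form comp, c and seq with numbers, a form used by the assembler Trinity for components and their sequences, and no genome coordinate goes with them.

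Each deposited file lists the same 14905 sequences in the same order with the same lengths. Per the file headers, the values are the read count of each sequence, the total reads of the library, the sequence length and an RPKM value. The RPKM that the authors deposited was checked against the file's own columns. It equalled the read count scaled per kilobase of length and by the stated library total, with a largest absolute difference of 3.8e-11. The deposited counts summed to 16829055 reads at 14 h, 16192136 at 45 h, 15690090 at 57 h and 15376509 at 88 h. These sums are 1.35, 1.36, 1.29 and 1.27 times the stated totals. Either some reads were counted on more than 1 sequence or the 2 columns count in different units, and the files do not say which. Counting intervals treat reads as independent, which PCR copies, read pairs and shared reads break, so they are too narrow.

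Groups were taken from the labelled culture time. The comparisons were 45, 57 and 88 h with 14 h, and the successive steps 14 to 45 h, 45 to 57 h and 57 to 88 h, which makes 5 distinct pairs. With 1 library per time, no test between single times could be made. A trend on culture time across the 4 libraries could have been fitted but was not run, so no gene-level test is given. The log2 ratio was taken on the authors' scale, as reads plus a pseudocount of 0.5 over the library total. Apart from the pseudocount, which matters at low counts, this equals a ratio of RPKM values. Sequences with a mean of at least 10 reads in the 2 libraries entered, and a ratio of at least 2-fold was counted. The 95% interval of a ratio is the exact conditional binomial (Clopper-Pearson) interval. Expected numbers from counting error came from 100 Poisson draws of libraries with equal composition at the observed totals. For every pair that composition was the mean over all 4 libraries, not over the 2 compared. The effective number of sequences is the exponential of the Shannon entropy of the read shares.

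The alternatives were edgeR's TMM effective library sizes, median-of-ratios size factors, a total without the 10 most abundant sequences, no floor, a floor of 50 reads, a pseudocount of 5 reads, and a rule that the whole counting interval lie beyond 2-fold. These, the comparisons and the rule for named sequences were chosen before the data were examined. A single sequence per component (the one with the most reads) and the sum of counts as library size were added after seeing the data, as were the abundance, length and component groups. For files without gene names, the rule names by identifier the 2 sequences with the highest and the 2 with the lowest ratio of 88 h to 14 h among those with a mean of at least 100 reads. The 20 gene lists fixed beforehand were patterns of gene names. None could be scored, because 0 of the 14905 sequences carries a name.

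The ratio and its interval were tested on simulated data with 200 changed sequences. In the simulation of 88 h against 14 h, run on 13959 sequences, 100% of 4-fold increases and 100% of 4-fold decreases were counted. So were 2% of 1.5-fold increases, 0% of 1.5-fold decreases and 0.538% of unchanged sequences. In that of 57 h against 45 h, run on 13944 sequences, 100% of 4-fold changes in either direction, 6% of 1.5-fold increases, 4% of 1.5-fold decreases and 0.466% of unchanged sequences were counted. The intervals held the true ratio for 95.5% and 95.7% of unchanged sequences. Apart from the changed sequences, both simulated libraries were Poisson draws from 1 shared composition. That is the model the interval assumes, so coverage near 95% followed from the setting. A shift of composition and reads shared between sequences were not simulated. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16 were used, the last for scaling factors only.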

Results

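RNA of a green microalga was sequenced at 4 times of a shake-flask culture, to characterise expression during growth of a strain studied for its lipid. The strain was UTEX2341, which the sample labels place in the species Neodesmus pupukensis and the series' design text names Chlorella minutissima. Cells were harvested after 14, 45, 57 and 88 h, and 1 library of total RNA represents each time. Whether the 4 harvests came from 1 flask or from several is not given in the sources used here. The label on lipid yield is worded identically for all 4 samples, so no relation between expression and lipid was computed. With 1 library per time, no difference below has a replicate check and no p-value was calculated. Each difference compares 2 libraries and was judged by its size, and intervals cover counting error only.

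Each library was described by reads on the same 14905 assembled transcript sequences, which belong to 6216 components, a component being the set of sequences that share the first part of their identifier. The sequences were 351 to 25689 bases long, with a median of 2270 bases. The files pair none of these identifiers with a gene name, a function or a genome position. The enzymes of lipid synthesis that the series title refers to were therefore not identified among them. The deposited library totals were similar, at 12495251 reads at 14 h, 11874560 at 45 h, 12130407 at 57 h and 12077745 at 88 h. Between 14616 and 14662 of the sequences had at least 1 read in a given library, and the 243 to 289 sequences at 0 reads could each have up to 3 reads per library within counting error. The median sequence had 251 reads at 14 h, 240 at 45 h, 135 at 57 h and 136 at 88 h.

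By correlation, the 4 libraries fell into an early and a late pair. Across all sequences, which are not independent replicates, the Spearman correlation of read counts was 0.965 between 14 h and 45 h and 0.988 between 57 h and 88 h. It was between 0.846 and 0.870 for each of the 4 pairs of an early with a late library. The 45 h and 57 h libraries, taken 12 h apart, correlated at 0.863, less than the 14 h and 45 h libraries, taken 31 h apart. Of the 100 most abundant sequences of each library, 68 were shared between 14 h and 45 h, 53 between 45 h and 57 h, and 89 between 57 h and 88 h. The 14 h list shared 64 with that of 57 h and 61 with that of 88 h, close to its 68 with 45 h, so these lists hardly set 14 h apart from the late libraries. The 45 h and 88 h lists shared 47.

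Transcript abundance became more concentrated in the late libraries. The sequence with the most reads in every library, 7253 bases long, took 1.59% of the library total at 14 h (95% exact binomial interval 1.58 to 1.59%), 3.46% at 45 h (3.44 to 3.47%), 5.35% at 57 h (5.34 to 5.36%) and 8.47% at 88 h (8.45 to 8.48%). Its RPKM, the read count scaled to sequence length and library total, went from 2186.8 at 14 h to 11671.7 at 88 h. The 10 most abundant sequences of each library took 5.24%, 7.8%, 12% and 13.3% of the reads counted on sequences at 14, 45, 57 and 88 h. The 100 most abundant took 21.5%, 23.2%, 35.3% and 37% in the same order. The median RPKM over all sequences was 10.3 at 14 h and 11.2 at 45 h, against 5.38 at 57 h and 5.52 at 88 h.

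**Figure D1:**
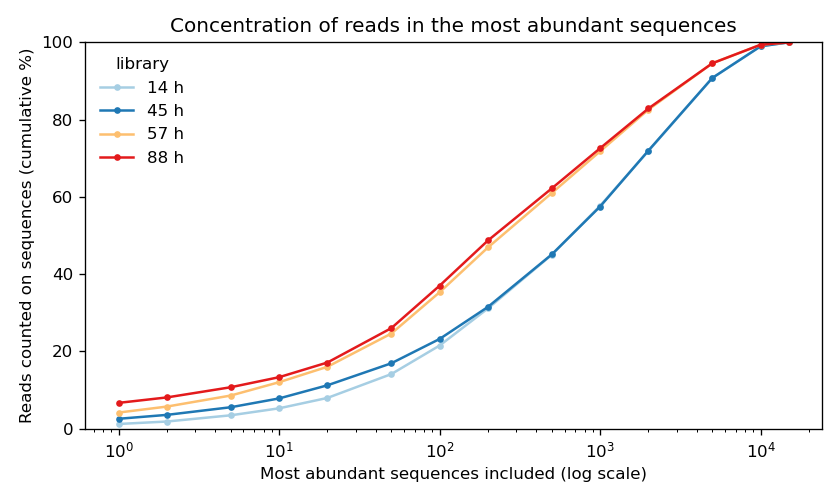
Cumulative share of the reads counted on sequences (percent) against the number of most abundant sequences included (log scale), 1 line per library. The lines of 57 h and 88 h lie above those of 14 h and 45 h, with 35.3% and 37% of reads in the top 100 sequences against 21.5% and 23.2%.

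The first step of the time course, from 14 h to 45 h, left most sequences within 2-fold. Of 13920 sequences with a mean of at least 10 reads in the 2 libraries, 1446 were at least 2-fold higher and 809 at least 2-fold lower at 45 h, together 16.2%. Changes of at least 8-fold were few, with 20 sequences higher and 2 lower. The median log2 ratio was -0.02, with quartiles of -0.43 and 0.43. Among the 100 sequences most abundant over the 4 libraries, 19 were at least 2-fold higher and 0 at least 2-fold lower, and their median log2 ratio was -0.43. Simulated libraries that differed by counting error alone gave a mean of 73.5 sequences 2-fold apart. When the whole counting interval had to lie beyond 2-fold, 784 sequences were higher and 336 lower.

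The 12 h between 45 h and 57 h held the largest difference of the 3 successive steps. Of 13963 sequences, 1652 were at least 2-fold higher and 5815 at least 2-fold lower at 57 h, together 53.5%. On the deposited scale, at least 8-fold differences were seen for 96 higher and 883 lower sequences. These counts are not centred on the median log2 ratio, which was -0.71. The 5th and 95th percentiles, -3.18 and 1.72, lay about equally far from that median. There were 24 sequences with 10 or more reads at 45 h and 0 reads at 57 h, and 11 with the opposite pattern. The 100 most abundant sequences went against the majority, with 54 of them at least 2-fold higher, 12 at least 2-fold lower and a median log2 ratio of 1.03, or 1.74 above that of all sequences. They were ranked by mean reads over the 4 libraries, a mean to which a sequence abundant in a single library can contribute much. Reads at 57 h enter that mean, so the ranking can favour sequences that are high there. Grouped by that mean, sequences below 65.9 reads had a median log2 ratio of -0.53, which is 0.18 above that of all sequences, and those above 838.1 reads one of -0.54, or 0.16 above. Sequences from 65.9 to 256.8 reads had a median of -0.82, and those from 256.8 to 838.1 reads one of -0.94, which relative to all sequences are -0.12 and -0.23.

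The split between higher and lower sequences at this step depended on the scale. On the deposited scale of reads per library total, the median log2 ratio of all sequences was -0.71, so a sequence at the median was lower at 57 h. Relative to that median, 3304 sequences were at least 2-fold higher and 3220 at least 2-fold lower. TMM scaling, which sets most sequences as unchanged on average, gave 3272 higher and 3250 lower. The share of higher sequences among all those 2-fold apart was 22.1% on the deposited scale and 50.2% with TMM. The sequences 2-fold apart numbered 7467 on the deposited scale and 6522 with TMM. Counting error alone gave a mean of 75 sequences.

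**Figure D2:**
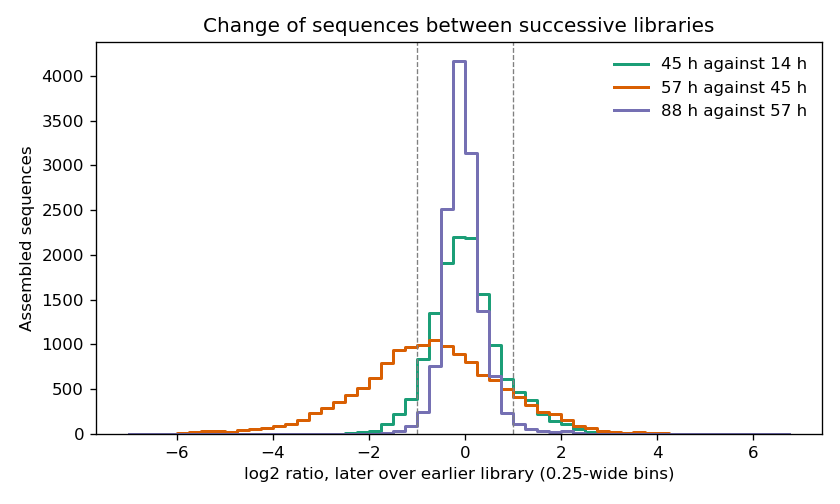
Number of sequences in 0.25-wide bins of the log2 ratio of the later over the earlier library, 1 line per successive step, with dashed lines at 2-fold. The 57 h against 45 h line is the widest and has its median at -0.71, while the 88 h against 57 h line is the narrowest, with quartiles of -0.27 and 0.16.

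From 57 h to 88 h few sequences differed. Of 13502 sequences, 282 were at least 2-fold higher and 150 at least 2-fold lower at 88 h, together 3.2%. At least 8-fold differences were limited to 3 higher sequences and 0 lower ones. None of the 100 most abundant sequences was 2-fold apart. Counting error alone gave a mean of 73.1 sequences, simulated from the mean composition of all 4 libraries. That value may be too low for this step. The median sequence had 135 reads at 57 h and 136 at 88 h, against 251 at 14 h and 240 at 45 h. No sequence was lower by more than 2-fold over its whole counting interval, while 99 were higher. The low-count sequences held most of the difference, since with a floor of 50 reads 130 sequences were higher and 16 lower.

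Compared with the 14 h library, the late libraries showed the same division. At 57 h 2018 sequences were at least 2-fold higher and 5911 at least 2-fold lower out of 13950, with a median log2 ratio of -0.72. At 88 h 1998 were higher and 6165 lower out of 13934, with a median of -0.79. Relative to those medians the counts were 3610 higher and 3379 lower at 57 h, and 3646 higher and 3317 lower at 88 h. With TMM scaling they were 3586 and 3405 at 57 h, and 3594 and 3370 at 88 h. The share of higher sequences among those 2-fold apart was 25.5% at 57 h and 24.5% at 88 h on the deposited scale, and 51.3% and 51.6% with TMM. The 100 most abundant sequences had median log2 ratios of 0.41 at 57 h and 0.54 at 88 h, with 25 at least 2-fold higher at each time and 11 and 10 at least 2-fold lower. The late libraries enter the mean by which these sequences were ranked, so the ranking can favour sequences that are high there.

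**Figure D3:**
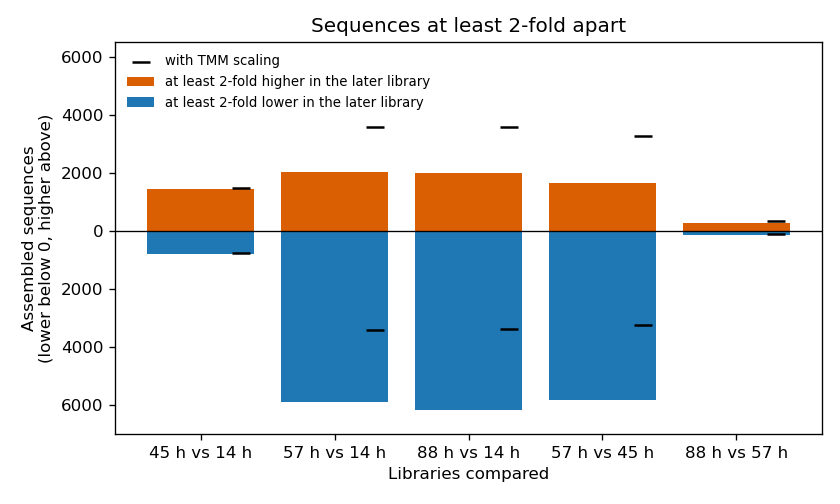
Number of sequences at least 2-fold higher (above 0) or lower (below 0) in the later library for the 5 comparisons, as bars on the deposited scale and black marks with TMM scaling. The 3 comparisons of a late with an early library hold 7467 to 8163 sequences 2-fold apart, against 2255 for 45 h with 14 h and 432 for 88 h with 57 h.

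Grouped by their course against 14 h, 13975 sequences with a mean of at least 10 reads over the 4 libraries fell mainly into 3 sets. A set of 4575 stayed within 2-fold at all later times. A set of 4509 was within 2-fold at 45 h and lower at 57 h and 88 h, and 1240 were within 2-fold at 45 h and higher at both late times. With TMM scaling these 3 sets held 5523, 2295 and 2481 sequences. A difference that was in the same direction at all 3 later times was less common, with 490 sequences higher and 621 lower, or 699 and 468 with TMM. All 3 comparisons share the 14 h library, and unchanged libraries simulated with counting error gave a mean of 7.11 sequences higher and 0.76 lower at all 3 times. Independent lists of the observed sizes would share 30.8 and 152.0 sequences. The 57 h and 88 h lists were far from independent. They shared 1750 higher and 5493 lower sequences, where independence gives 290.7 and 2615.4. The values of 30.8 and 152.0 are therefore low marks for the overlap of all 3 lists. Part of the excess may also come from the shared 14 h library, which, being single, could not be split.

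Some sequences departed from 14 h only in the 45 h library, or turned after it. There were 393 sequences at least 2-fold higher at 45 h and within 2-fold of 14 h at both late times, and 125 that were lower at 45 h alone. A further 363 were at least 2-fold higher at 45 h and at least 2-fold lower than at 14 h at both late times, and 20 showed the opposite course. Counting error alone gave means of 18.5, 32.1, 0.01 and 0.02 for these 4 sets. With TMM scaling they held 452, 198, 196 and 40 sequences.

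The sequences with the most extreme ratios of 88 h to 14 h, among those with a mean of at least 100 reads, had few reads in the library where they were lowest. The 2 highest were comp5016_c0_seq1 and comp625_c0_seq1, and the 2 lowest comp5143_c0_seq1 and comp3215_c0_seq1. The counting intervals overlapped within each pair, so neither pair has an order, and with a pseudocount of 5 reads comp3215_c0_seq1 (-6.51) lay below comp5143_c0_seq1 (-6.15). The sequence comp5016_c0_seq1, of 387 bases, had 16 reads at 14 h, 18 at 45 h, 1459 at 57 h and 937 at 88 h. Its RPKM was 3.31, 3.92, 310.8 and 200.5 in that order. With the pseudocount, its log2 ratio of 88 h to 14 h was 5.88, with a 95% counting interval of 5.21 to 6.73. The sequence comp625_c0_seq1, of 918 bases, had an RPKM of 1.13, 1.83, 50 and 52.4 and a log2 ratio of 5.48 (4.75 to 6.45). Among the lowered pair, comp5143_c0_seq1, of 1659 bases, had 509 reads at 14 h, 93 at 45 h, 4 at 57 h and 2 at 88 h, a log2 ratio of -7.62 (-10.99 to -6.08). The other, comp3215_c0_seq1, of 2140 bases, had an RPKM of 115.9, 52.1, 0.732 and 1.08 and a log2 ratio of -6.72 (-7.33 to -6.21). In all 4 sequences the log2 ratio of 57 h to 45 h was the largest of the 3 steps, at 6.27 and 4.73 for the first pair and -4.41 and -6.12 for the second. The 2 lowered sequences were already lower at 45 h, with log2 ratios to 14 h of -2.37 and -1.15. The 2 raised ones had ratios of 0.24 and 0.68. These rest on 16 and 18 reads at 14 h and 45 h for comp5016_c0_seq1, and on 13 and 20 for comp625_c0_seq1. Counting error is large at so few reads.

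Sequences from components of different size were compared as a further grouping. At the step from 45 h to 57 h, the 3147 sequences that were alone in their component had a median log2 ratio of -0.92, with 414 at least 2-fold higher and 1519 at least 2-fold lower. The 10816 sequences from components of 2 or more had a median of -0.66, with 1238 higher and 4296 lower. The 3799 from components of 10 or more, which are part of that group, had a median of -0.37, with 607 higher and 1092 lower. The largest component has 212 sequences, so a few large components can weigh heavily in this median. Relative to the median of all sequences these 3 medians are -0.21, 0.05 and 0.34. Sequences of 1 component are not independent, because reads may be counted on several of them.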

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

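The order of the 3 successive steps, with 45 to 57 h above 14 to 45 h and 57 to 88 h lowest in sequences 2-fold apart, held under all 9 alternatives. The totals ranged over alternatives from 1036 to 2611 for 14 to 45 h and from 3261 to 7907 for 45 to 57 h. Both low ends come from 1 sequence per component, where fewer sequences enter. As shares of the sequences entering, that setting gave the highest values for these 2 steps. They were 18.6% and 58.4%, against 16.2% and 53.5% as reported. Of 106 alternative counts, 72 stayed within 1.5 times the reported count. TMM scaling gave 3586 higher and 3405 lower at 57 h against 14 h, 3594 and 3370 at 88 h against 14 h, and 3272 and 3250 at 57 h against 45 h. Median-of-ratios factors gave 3599 and 3395, 3645 and 3322, and 3309 and 3204 for the same pairs. Both scalings place the typical sequence at no change by construction, which moved the split. For 88 h against 57 h, 492 were higher and 351 lower with no floor, 130 and 16 with a floor of 50 reads, and 58 were lower with a pseudocount of 5 reads. The floor of 50 reads also left 302 sequences higher at all 3 later times. With the whole counting interval beyond 2-fold, 784 were higher and 336 lower at 45 h against 14 h, and 99 higher and 0 lower at 88 h against 57 h. With 1 sequence per component, an alternative chosen after seeing the data that enters fewer sequences, the counts higher and lower were 620 and 416 at 45 h, 702 and 2657 at 57 h and 747 and 2700 at 88 h, all against 14 h. They were 636 and 2625 at 57 h against 45 h, 106 and 41 at 88 h against 57 h, and 168 and 335 at all 3 later times. Of the 4 named sequences, chosen for extreme ratios, comp5143_c0_seq1 went from a log2 ratio of -7.62 to -6.15 with a pseudocount of 5 reads, and comp3215_c0_seq1 from -6.72 to -6.51, which reversed their order. The ratio of comp3215_c0_seq1 was -5.94 with TMM and -5.92 with median-of-ratios factors, the last 2 values lying outside its counting interval. With TMM comp5016_c0_seq1 was at 6.65, comp625_c0_seq1 at 6.25 and comp5143_c0_seq1 at -6.85. Alternatives planned for the gene lists were not run, because no list could be scored, and no library could be left out with 1 per time. No paired analysis was possible because each time has 1 library. Depth limits the 57 to 88 h step most, since 432 sequences were 2-fold apart there and counting error alone gave up to 99. The latter may be too low for this step, because the simulated composition was the mean of all 4 libraries.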

Other observations

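The tests of length, of library batch, of depth and of the median shift were chosen after the results were seen. The depth test replaced a planned and an added thinning of reads. Both thinnings hardly moved any value, and no conclusion is drawn from them here. The other tests were written down before their results.

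Sequences of the same component moved together between 45 h and 57 h. In 2409 components with 2 or more sequences over the floor, the median standard deviation of the log2 ratio within a component was 0.11, against 1.20 in random groups of the same sizes. In 38 components, or 1.58%, 1 member was at least 2-fold higher and another at least 2-fold lower, where shuffling the ratios over sequences gave a mean of 624.7. These 38 are the places where sequences of 1 component went opposite ways across the step with the largest difference. Reads counted on several sequences of a component could produce the agreement. In the 1115 components whose members' counts lay within 1.5-fold of each other in every library, the spread was 0.02. In the 520 whose members were over 3-fold apart in every library it was 0.41, or 30.8% of the 1.32 in random groups. The bound set beforehand for excluding shared reads, 60%, was ill chosen, since a member with 3-fold more reads can still hold every read of the smaller one, so shared counting stays open for these components.

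The difference between the 45 h and 57 h libraries was set against 3 technical explanations. A few sequences taking most of the counts would move all others by 1 factor, but with TMM scaling 6522 sequences were 2-fold apart at this step, against 2260 and 447 at the other steps, which argues against it as the whole cause. The same holds for a length bias: after the median of each of 20 length bins was removed, 93.7% of the 6524 sequences at least 2-fold from the overall median were still so, and the Spearman correlation of ratio with length was 0.07. A library or sequencing batch that parts 14 h and 45 h from 57 h and 88 h cannot be told apart from culture time, because each time has only 1 library and the labels give no batch. A change of the cells with culture time therefore stays open as the biological explanation that the design names, and was not tested.

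Fewer sequences carried the reads of the 57 h and 88 h libraries, and the median RPKM was lower in these than at 14 h and 45 h. The effective number of sequences was 3519 at 14 h, 3300 at 45 h, 1748 at 57 h and 1567 at 88 h, and 3938, 4080, 2407 and 2356 after the 10 most abundant sequences of each library were left out. Reads counted on several sequences of a component are argued against, since with 1 sequence per component the number at 88 h was 40.5% of that at 14 h (642 against 1588). The test of depth by library totals does not decide by itself, because its outcome depends on the total used. The 45 h library had the lowest library total (11874560 reads, against 12130407 at 57 h) and an effective number 1.89 times that at 57 h. By reads counted on sequences, which enter the effective number, the late libraries were lowest. These were 15690090 at 57 h and 15376509 at 88 h, against 16192136 at 45 h and 16829055 at 14 h. The gap in counted reads is small beside that in effective number. Counted reads fell by more from 14 h to 45 h than from 45 h to 57 h. Yet the effective number went from 3519 to 3300 over the earlier step and from 3300 to 1748 over the later one. These values argue against depth as the whole cause. The median shift at 57 h against 45 h was also measured with the sum of counts as library size. Leaving out each library's 100 most abundant sequences moved the median log2 ratio from -0.63 to -0.39. The concentration of reads runs past rank 100. The top 500 sequences held 45.1% of counted reads at 45 h and 61% at 57 h, and the top 1000 held 57.5% and 71.8%. The cut at 100 therefore cannot show how much of the shift comes from abundant sequences as a whole. Depth as a part of the cause was not excluded, and a batch and culture time stay open here too.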
